A study of Mus musculus with 6 samples.

How the data were processed

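The data are RNA sequencing libraries from suspensions of STRA8+ cells of mouse testis, 3 from Cre controls and 3 from conditional knockout animals. Samples were grouped by the titles in the labels, which also number the replicates. The labels' extraction protocol speaks of retinas while every other label names testis, so a list of photoreceptor genes was included as a check of the tissue. Reads were aligned with HISAT2 2.0.5 to mm10, per the submitters' processing notes. The counter, the annotation release and any treatment of strand and of reads that map to several places are not given in the sources used here, so values of near-identical copies and of overlapping or antisense genes are uncertain.

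The authors deposited FPKM values (fragments per kilobase of gene length and per 1000000) for 54532 genes in the 6 libraries, with gene lengths, coordinates and biotypes. Multiplied by gene length, the FPKM gave whole multiples of the value of 1 read in each library for 100% of the nonzero genes, within 0.01 read, so the reads behind each value were recovered. The totals were 14532453, 16963019 and 16410857 reads in the controls and 15204127, 14770320 and 14806917 in the knockout. The library divisor behind the deposited FPKM was not the library's total. It equalled a median-of-ratios size factor over the 19526 genes with reads in every library, times the geometric mean of the totals. The divisors were 0.691, 0.774 and 0.751 times the recovered total in the controls and 1.42, 1.37 and 1.40 times in the knockout. The deposited values therefore compare libraries as that size factor sets them, and knockout values are lower against control values than shares of reads would be. Of the gene identifiers, 54409 were also in GENCODE M21, and 53499 of those had the same chromosome, start and end there. Coordinates are 1-based, as the deposited table gives them.

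Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 16791 in all. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), knockout minus control, with empirical Bayes moderation and a mean-variance trend, Benjamini-Hochberg adjustment and a threshold of adjusted p of 0.05. Standard errors are the moderated ones. Means, SDs and folds in FPKM are of the deposited values. Intervals of read ratios are exact 95% intervals and cover counting error only, since the reads carry no molecular identifiers. Where a group had 0 reads, the floor was 3 reads over the group. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.

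A set of 32 gene lists was fixed before the data were examined: the 2 title genes, splicing, break formation, recombination, synapsis, meiotic entry, germ cell stages, piRNA, p53, cell cycle, interferon, immediate-early and heat shock genes, somatic testis cells, blood cells, photoreceptors, histones, both sex chromosomes, the mitochondrial genome and ribosomal proteins. The 28 lists with at least 5 genes tested went into camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; the title genes and the endothelial, erythroid and photoreceptor lists had too few. Camera calls 20 of the 28 lists, and none of these calls holds with an estimated correlation. Fry, which asks whether a list moves one way, was a further alternative. Counts adjusted over the list alone use the Benjamini-Hochberg method on the list's own p-values. Of the photoreceptor genes, 4 of 19 passed the filter, and the list took 0.00444% of the control reads and 0.00254% of the knockout reads.

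The rule for named genes was also fixed before the data were examined. It always took Bcas2 and Hnrnph1. It then took the 8 largest rises and the 8 largest falls among protein-coding genes past the threshold, with an absolute log2 fold change of at least 1, groups that do not overlap, at least 5 FPKM in the higher group and a gene name that is not a predicted or clone name. From each list tested it took up to 4 members with the smallest p (2 from the chromosome, mitochondrial and ribosomal lists). It gave 116 genes, of which the text gives those that stand for their group.

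Alternatives to the gene model, fixed before the data were examined, were other pseudocounts (0.1 and 1), no filter or a filter at 5 FPKM, 3 other scalings, no trend, array weights, the replicate number as a block, limma voom on the recovered reads, protein-coding genes alone, a fold change threshold and leaving out each library. Removing the size factor was added after the data were seen, as was leaving out 1 doubtful list member. The main test stayed on FPKM, the deposited unit. Of models for counts, only limma voom was run on the recovered reads, and it called 14517 genes, 6148 higher and 8369 lower. The model was tested on simulated libraries of 15320 genes tested, drawn for knockout against control with 200 genes changed. They used the control means, the real library sizes and a common dispersion of 0.0117 for all genes. The model recovered 34.4% of the 1.5-fold changes, 90% of the 2-fold changes and 100% of the 4-fold changes, with 7 false calls. With so few genes changed, the simulation does not cover the wide change and the dependence on scaling of the real libraries. Splicing itself, which the title concerns, was not analysed here, because the table holds one value per gene.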

Results

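Messenger RNA levels were measured by sequencing in 6 libraries made from cell suspensions of mouse testis that the labels describe as STRA8+. STRA8 marks germ cells that are entering meiosis under retinoic acid. A group of 3 control libraries carried the Cre recombinase, and a group of 3 knockout libraries came from conditional knockout animals. The labels do not say which gene was deleted. The title of the study names BCAS2 and hnRNPH1 and concerns splicing, repair of DNA double-strand breaks and synapsis in meiotic prophase I. The single comparison of the design, knockout against control, asks which transcripts changed with the deletion. The reads behind each library's values totalled 14532453, 16963019 and 16410857 in the controls and 15204127, 14770320 and 14806917 in the knockout. A level of at least 1 FPKM was reached by 16653 to 16877 genes per control library and by 13077 to 13235 genes per knockout library. Levels are given below as mean ± SD over the 3 libraries of a group, and fold changes are on the log2(FPKM + 0.5) scale, which understates the change of genes with low values.

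Bcas2, which encodes a subunit of the PRP19 splicing complex, was about 4 times lower in the knockout. Its level was 19.9 ± 0.586 FPKM in the controls (SD, n = 3) and 4.85 ± 0.515 FPKM in the knockout (SD, n = 3). The control libraries gave 19.8, 19.3 and 20.5 FPKM and the knockout libraries gave 4.78, 4.38 and 5.40 FPKM. Hnrnph1, which encodes an RNA-binding regulator of splicing, was higher, at 63.8 ± 3.26 FPKM in the controls and 140.1 ± 14.04 FPKM in the knockout. The log2 fold change was -1.93 ± 0.105 (SE) for Bcas2 with a limma adjusted p of 7.6e-07, and 1.13 ± 0.0987 (SE) for Hnrnph1 with a limma adjusted p of 1.3e-05. Bcas2 (ENSMUSG00000005687) lies on chromosome 3 at 103171655 to 103179166 and Hnrnph1 (ENSMUSG00000007850) on chromosome 11 at 50376990 to 50386528 in mm10, the build in the submitters' processing notes, and both are annotated as protein-coding. The values cover whole genes, so they do not show whether any exon of either gene was removed. Both sizes moved with the scaling: with FPKM rescaled to sum to 1000000 per library the log2 fold changes were -0.84 and 2.32. Of the 16791 genes tested, 6898 passed the threshold with a log2 fold change of -1 or less as deposited. The size of its fall alone therefore does not mark Bcas2 as the deleted gene.

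**Figure D1:**
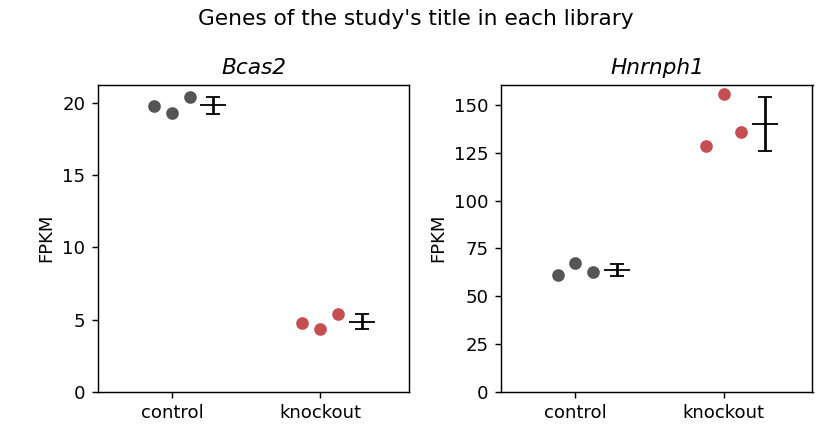
FPKM of Bcas2 (left) and Hnrnph1 (right) in each library, with points for the 3 control and 3 knockout libraries and a bar for the group mean ± SD. The knockout libraries lie between 4.38 and 5.40 FPKM for Bcas2, below the controls at 19.3 to 20.5, and between 128.8 and 155.8 FPKM for Hnrnph1, above the controls at 61.2 to 67.5.

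The knockout libraries differed from the controls across most of the transcriptome. Among the lists tested, spermatid markers had the lowest median. Most genes tested from the lists of spermatogonia, meiotic initiation, break formation and Sertoli cells rose. Of 16791 genes tested with limma, 14537 passed an adjusted p of 0.05, with 6075 higher and 8462 lower in the knockout. At an absolute log2 fold change of at least 1, 3920 were higher and 6898 lower. The median log2 fold change of all genes tested was -0.41 as deposited. Other scalings raised it by 1.12 (FPKM rescaled to sum to 1000000), 0.94 (quantile normalization) or 0.83 (reads rescaled to 1000000, an alternative added after the data were seen), and gave splits of 9109 higher and 6084 lower, 8745 and 6187, and 8491 and 6527. Median-of-ratios factors from the genes tested raised it by 0.04. A total of 11820 genes were called in the same direction under the deposited scaling and 4 other scalings, 6074 of them higher and 5746 lower. Several list medians are therefore also given relative to the median of all genes. Those of the chromosome axis, G2 and M phase and histone lists, negative as deposited, were 0.41, 0.29 and 0.32 relative to it. The replicates of a group correlated across genes, which are not independent, with Pearson r of 0.969 to 0.987 on the log2 scale, and libraries of different groups with r of 0.172 to 0.285. Replicates still differed beyond sampling noise, with a chi-square of 7.55 to 14.7 per gene on the recovered reads. The labels do not say whether the libraries came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

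The 8 named genes with the largest falls included protamines and proteins of the sperm tail. Prm1 and Prm2, the protamines that package sperm DNA, went from 5293 ± 696.5 and 3287 ± 109.8 FPKM in the controls to 0.398 ± 0.270 and 0.479 ± 0.830 FPKM in the knockout. Tnp2, a transition protein of condensing spermatid nuclei, went from 4465 ± 654.6 to 0.897 ± 0.677 FPKM. Smcp, a protein of the sperm mitochondrial capsule, Odf1 of the outer dense fibers and Akap4 of the fibrous sheath fell from 2439 ± 219.8, 1554 ± 188.8 and 895.9 ± 128.0 FPKM to 0.307 ± 0.531, 0.348 ± 0.137 and 0.0921 ± 0.121 FPKM. Gsg1 and Spz1 completed the 8, with log2 fold changes of -10.65 and -10.64. The knockout values rest on few reads: Prm1 had 106017 reads in the 3 controls and 14 in the 3 knockout libraries, a scaled ratio of 13350 with an exact 95% interval of 7958 to 24420 that covers counting error only. All knockout reads of Prm2, Smcp, Gsg1 and Spz1 came from knockout replicate 2.

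All 28 spermatid markers fell, as they did when adjusted over the list alone, with a median log2 fold change of -8.22 (-7.81 relative to all genes). Oaz3, an ornithine decarboxylase antizyme of haploid cells, fell from 274.3 ± 19.3 to 0.333 ± 0.0389 FPKM, and Txndc2, a sperm thioredoxin, from 274.8 ± 13.99 to 0.394 ± 0.0272 FPKM. Camera, limma's test of a list against the other genes, gave an adjusted p of 7.2e-09, and adjusted p = 0.493 with an estimated correlation. Spermatid markers took 2.07 ± 0.0497% of the reads in the controls and 0.0385 ± 0.00114% in the knockout, although the labels name a STRA8+ population for both groups. With the 1 member that had no knockout reads placed at a floor of 3 reads over the group, the median log2 ratio of scaled reads was -10.73.

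Markers of pachytene and diplotene spermatocytes fell in 33 of 34 genes tested and rose in 1, with the same counts when adjusted over the list alone and a median log2 fold change of -5.66 (-5.24 relative to all genes). Pgk2, the testis form of a glycolytic kinase, fell from 776.7 ± 112.1 to 0.130 ± 0.128 FPKM. Tdrd6, a component of the chromatoid body, fell from 207.0 ± 23.4 to 0.217 ± 0.0926 FPKM, and Tekt1 and Spata16 fell with log2 fold changes of -8.00 and -8.35. The member that rose was Slc25a31, a mitochondrial ADP/ATP carrier, at 59.3 ± 2.07 and 111.0 ± 8.61 FPKM; it was named after its value was seen. Camera gave an adjusted p of 1.9e-07 for the list, and adjusted p = 0.493 with an estimated correlation. Of 25 genes of the piRNA pathway, which silences transposons in germ cells, 17 fell and 7 rose, as when adjusted over the list alone, and 12 fell and 9 rose with FPKM rescaled to sum to 1000000. Piwil1 fell from 134.0 ± 12.1 to 2.94 ± 0.545 FPKM and Gtsf1 from 220.2 ± 20.5 to 13.3 ± 0.787 FPKM, while the list as a whole had a camera adjusted p of 0.159, or 0.048 among protein-coding genes alone and 0.041 with no filter, and fry placed it on the lower side with an adjusted p of 0.00011.

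Markers of differentiating spermatogonia rose in 16 of 20 genes and fell in 1, as when adjusted over the list alone, with a median log2 fold change of 2.05 (2.47 relative to all genes). Stra8, which the cell label refers to, rose from 17.0 ± 5.55 to 132.8 ± 6.42 FPKM, Crabp1, a retinoic acid binding protein, from 10.6 ± 2.81 to 70.7 ± 7.66 FPKM and the X-linked homeobox gene Rhox13 from 6.001 ± 1.617 to 37.7 ± 3.86 FPKM. The gene that fell was Dmrtb1, a transcription factor of the switch from mitosis to meiosis, which went from 388.3 ± 53.8 to 26.0 ± 2.88 FPKM. Camera gave an adjusted p of 0.00011, and adjusted p = 0.493 with an estimated correlation. Markers of undifferentiated spermatogonia rose in 10 of 14 genes and fell in 2, as when adjusted over the list alone, with a median of 1.32 (1.73 relative to all genes). Uchl1, a deubiquitinase of spermatogonia, rose from 39.0 ± 8.10 to 235.4 ± 36.4 FPKM and Zbtb16 from 1.16 ± 0.130 to 6.51 ± 0.969 FPKM, while Id4, a marker of stem spermatogonia, fell from 10.8 ± 0.858 to 2.92 ± 0.419 FPKM. Camera gave an adjusted p of 0.011, and adjusted p = 0.493 with an estimated correlation.

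**Figure D2:**
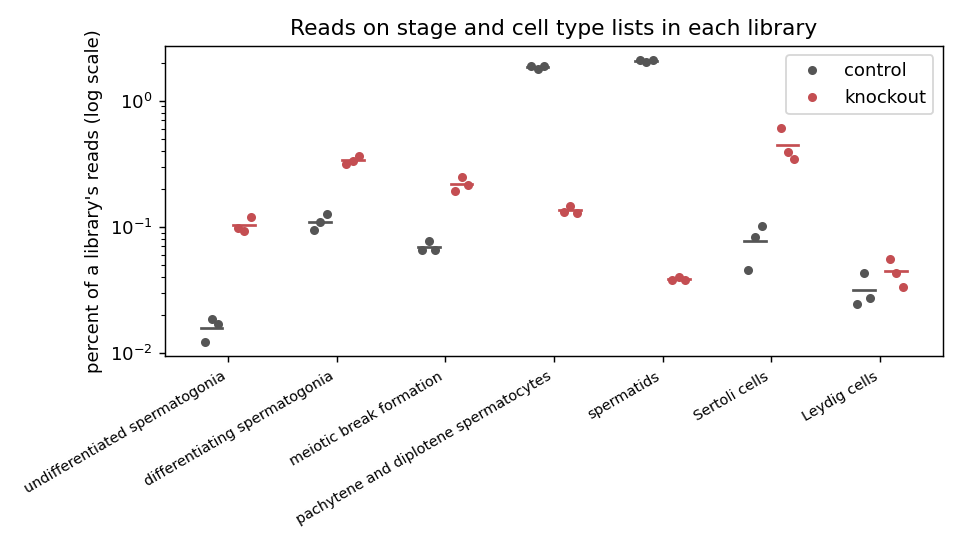
Percent of each library's reads on 7 stage and cell type lists, on a log axis, with points for libraries and lines for group means. Spermatid markers take 2.07% of control reads and 0.0385% of knockout reads on average, while differentiating spermatogonia markers take 0.110% and 0.338%. The differentiating spermatogonia list includes Dmrtb1, which fell and has the most control reads of its genes (28566 in the controls and 3385 in the knockout).

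Most genes tested from the meiotic initiation and break formation lists rose. Among 11 genes of meiotic initiation, 8 rose and 2 fell, as when adjusted over the list alone. Gm4969, the symbol in the deposited table for Meiosin, the partner of STRA8, rose from 7.74 ± 2.33 to 61.6 ± 8.68 FPKM, while Rec8, which encodes a meiotic cohesin, fell from 38.9 ± 5.06 to 11.7 ± 0.708 FPKM. The list's median log2 fold change was 1.06 (1.48 relative to all genes). Its camera adjusted p was 0.048, and adjusted p = 0.522 with an estimated correlation. Leaving out control replicate 3 or knockout replicate 2 also ended this call, at adjusted p of 0.064 and 0.060, as did FPKM rescaled to sum to 1000000 (0.084), reads so rescaled (0.073), quantile normalization (0.073), no trend (0.055) and protein-coding genes alone (0.116).

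In the machinery of meiotic break formation, 9 of 12 genes rose and 2 fell, as when adjusted over the list alone, with a median of 1.24 (1.65 relative to all genes). Prdm9, which marks the sites of breaks, rose from 3.07 ± 0.708 to 23.0 ± 3.09 FPKM and Zcwpw1, a reader of those marks, from 8.05 ± 1.66 to 35.8 ± 3.89 FPKM. Spo11, the enzyme that makes the breaks, fell from 26.3 ± 1.63 to 6.13 ± 0.483 FPKM. The other gene that fell, Ankrd31, was named after its value was seen and had log2 fold changes of -0.50 as deposited and 0.67 with FPKM rescaled to sum to 1000000. By camera the list had an adjusted p of 0.0080, and adjusted p = 0.522 with an estimated correlation.

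Of 58 genes of meiotic recombination and repair, 32 rose and 15 fell, as when adjusted over the list alone, with a median of 0.46 (0.88 relative to all genes). With FPKM rescaled to sum to 1000000, 47 rose and 6 fell, and with reads so rescaled 45 rose and 9 fell. The 4 members named for this list, taken by smallest p, all fell, although more members rose than fell. They include 1700034J05Rik. Prdm9, named for break formation and also a member, rose. Slx4, a scaffold of structure-specific nucleases, fell from 41.9 ± 2.52 to 6.20 ± 0.471 FPKM. The crossover factors Cntd1 and Prr19 fell from 16.9 ± 1.012 and 63.4 ± 6.74 FPKM to 2.48 ± 0.512 and 13.9 ± 1.66 FPKM. The camera adjusted p was 0.0080, and adjusted p = 0.626 with an estimated correlation. One member, 1700034J05Rik, may not be the gene that was meant, and without it 14 of 57 genes fell, with a camera adjusted p of 0.0049, and adjusted p = 0.620 with an estimated correlation. Genes of the chromosome axis and synaptonemal complex were divided, with 9 of 24 higher and 9 lower, as when adjusted over the list alone. The central element genes Syce1 and Syce3 had 302.4 ± 26.4 and 97.4 ± 11.8 FPKM in the controls and 64.8 ± 6.46 and 35.5 ± 1.30 FPKM in the knockout, while 4930447C04Rik, the table's symbol for Six6os1, another central element gene, rose from 9.14 ± 1.503 to 43.8 ± 7.86 FPKM. The fall of Syce3 was not kept under quantile normalization, where its log2 fold change was 0.04. The list's median was -0.01, its mean 0.07 and its camera adjusted p 0.387. With FPKM or reads rescaled to sum to 1000000 and under quantile normalization its median turned positive, between 0.89 and 1.22, and camera called it, with adjusted p of 0.017 to 0.048.

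Splicing factors rose more often than they fell. In the spliceosome core 27 of 46 genes rose and 10 fell, among hnRNP proteins 18 of 28 rose and 8 fell, and among SR proteins and their regulators 14 of 25 rose and 5 fell, all as when adjusted over the list alone. Snrnp70, of the U1 particle, rose from 15.4 ± 0.961 to 34.5 ± 2.63 FPKM, Raly from 17.7 ± 1.19 to 66.2 ± 1.39 FPKM and Srsf2 from 48.1 ± 6.86 to 150.3 ± 13.2 FPKM. The kinases Srpk1 and Srpk2, which phosphorylate SR proteins, fell from 46.8 ± 3.86 and 39.8 ± 1.05 FPKM to 11.5 ± 1.05 and 9.73 ± 0.992 FPKM. With FPKM rescaled to sum to 1000000 none of the spliceosome core and hnRNP genes was called lower by limma (0 and 0), and 2 SR genes were, with 43, 26 and 23 called higher. Camera gave adjusted p of 0.0015, 0.0038 and 0.0093 for the lists in that order, and adjusted p = 0.493 with an estimated correlation for each. The PRP19 complex itself was divided, with 8 of 19 genes higher and 7 lower, as when adjusted over the list alone, and a camera adjusted p of 0.396. Prpf19 rose from 9.23 ± 1.20 to 29.5 ± 1.19 FPKM, while Wbp11 and Ctnnbl1 fell from 170.0 ± 23.8 and 57.2 ± 4.82 FPKM to 23.2 ± 0.267 and 21.7 ± 0.915 FPKM. The fall of Ctnnbl1 did not pass with FPKM rescaled to sum to 1000000 or under quantile normalization. With FPKM rescaled to sum to 1000000, 15 of the 19 genes were higher and 2 lower. The PRP19 list's median was 0.12, and fry, which asks whether members move one way on balance, placed it on the lower side with an adjusted p of 0.032.

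The genes with the largest rises came from several classes. Ccl8, a chemokine, had 93.1, 10.2 and 19.6 FPKM in the knockout libraries and 2.34, 1.79 and 0.635 FPKM in the controls, so its mean of 40.95 ± 45.4 FPKM rested largely on knockout replicate 1. Cwc22, a spliceosome protein, rose from 2.56 ± 0.171 to 36.3 ± 0.675 FPKM. The number of Cwc22 copies varies between mouse strains, and the labels do not give the strain, so reads from further copies cannot be set apart. Sox3, a transcription factor of spermatogonia, rose from 3.56 ± 0.927 to 34.3 ± 5.54 FPKM. Rpl36a, a ribosomal protein gene, Dusp9, a phosphatase of MAP kinases, Edn1, which encodes endothelin, and Kif26a rose with log2 fold changes of 2.93, 2.91, 2.91 and 2.91. Stra8 was the remaining gene of the 8.

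Genes of the p53 response and apoptosis rose in 25 of 29 cases and fell in 2, as when adjusted over the list alone, with a median of 1.63 (2.04 relative to all genes). Trp53 itself rose from 3.65 ± 0.569 to 12.3 ± 0.266 FPKM and Trp53inp1, a proapoptotic target of p53, from 5.72 ± 0.879 to 22.1 ± 2.07 FPKM. Zmat3, another target of p53, fell from 3.31 ± 0.298 to 0.309 ± 0.0328 FPKM. The second gene that fell was Mdm2, which encodes the ubiquitin ligase of p53; it was named after its value was seen, and its log2 fold change was -1.17 as deposited and 0.00 with FPKM rescaled to sum to 1000000. In camera the adjusted p was 8.1e-06, and adjusted p = 0.493 with an estimated correlation. The median of this list was near that of the Sertoli markers, at 1.62. Whether its rise came from a p53 response or from a change in the mix of cells was not tested. Genes of S phase rose in 17 of 26 cases and fell in 2, as when adjusted over the list alone, with a median of 1.02 (1.44 relative to all genes). Mcm5, a subunit of the replicative helicase, rose from 9.99 ± 2.21 to 59.3 ± 3.17 FPKM, while Chaf1a, a chromatin assembly factor, fell from 28.6 ± 2.69 to 5.96 ± 0.401 FPKM. For this list camera returned an adjusted p of 0.00037, and adjusted p = 0.493 with an estimated correlation. Genes of G2 and M phase were divided, with 12 of 28 higher and 12 lower, as when adjusted over the list alone. Ccnb2 and Plk1 fell from 165.7 ± 20.8 and 64.8 ± 6.13 FPKM to 29.1 ± 3.64 and 19.01 ± 3.35 FPKM, and Ccnb3, a cyclin of early meiosis, rose from 2.09 ± 0.602 to 15.1 ± 2.09 FPKM. The G2 and M list's median was -0.12, and its camera adjusted p was 0.372 on the upper side. In the same 3 scalings, FPKM or reads rescaled to sum to 1000000 and quantile normalization, its median turned positive, between 0.77 and 1.05, and camera called it, with adjusted p of 0.017 to 0.030.

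Markers of somatic testis cells were present in both groups, and as deposited their lists did not move alike. With FPKM rescaled to sum to 1000000, all 22 Sertoli, 11 stroma and 15 macrophage and leukocyte markers tested rose. So did 6 of 8 myoid markers, but only 3 of 11 Leydig markers. With reads so rescaled, the counts in that order were 22, 11, 14, 5 and 3. All 22 Sertoli markers tested rose, as when adjusted over the list alone, with a median of 1.62 (2.04 relative to all genes). Inha, which encodes an inhibin subunit, rose from 27.5 ± 7.71 to 117.6 ± 28.3 FPKM, Defb19 from 90.8 ± 10.2 to 178.2 ± 11.3 FPKM and Shbg from 2.30 ± 0.827 to 16.1 ± 5.14 FPKM. By camera the list had an adjusted p of 8.1e-06, and adjusted p = 0.504 with an estimated correlation. Sertoli markers took 0.0769 ± 0.0288% of the control reads and 0.448 ± 0.138% of the knockout reads. The reads of Leydig markers took 0.0314 ± 0.00987% and 0.0443 ± 0.0113%, so their share was not lower in the knockout. Of 11 Leydig markers, 5 fell and 1 rose, or 4 and 1 when adjusted over the list alone. With FPKM rescaled to sum to 1000000, 2 fell and 3 rose, and with reads so rescaled 3 fell and 3 rose. Cyp17a1, an enzyme of androgen synthesis, fell from 37.6 ± 7.95 to 7.49 ± 5.66 FPKM and Cyp11a1, which makes pregnenolone, from 6.70 ± 1.36 to 2.22 ± 0.553 FPKM; the fall of Cyp11a1 did not pass with FPKM rescaled to sum to 1000000. The Leydig list's median was -0.78, but 0.31 with FPKM rescaled to sum to 1000000 and 0.06 with reads rescaled to 1000000, and its camera adjusted p was 0.723.

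Stroma markers rose in 7 of 11 cases, as when adjusted over the list alone, with Col1a1, a collagen of connective tissue, at 1.96 ± 0.596 and 6.47 ± 0.646 FPKM. The camera adjusted p was 0.013, and adjusted p = 0.493 with an estimated correlation. Macrophage and leukocyte markers rose in 7 of 15 cases and in 0 when adjusted over the list alone. C1qc, a complement component, had 5.52 ± 1.17 FPKM in the controls and 14.9 ± 9.94 FPKM in the knockout. That list's camera adjusted p was 0.014, with adjusted p = 0.660 with an estimated correlation, its median of 1.02 was 0.50 without knockout replicate 1, and the list was not called under quantile normalization (adjusted p of 0.057). The rise of C1qc did not pass without control replicate 1 or 3 (adjusted p of 0.097 and 0.084), with no filter (0.058) or with array weights (0.067), and its log2 fold change of 1.18 was 0.69 without knockout replicate 1. Among 8 myoid cell markers 1 rose and 1 fell, as when adjusted over the list alone, with a median of 0.20, a mean of -0.56 and a camera adjusted p of 0.479. The gene that fell was Actg2, a smooth muscle actin, from 168.8 ± 28.2 to 1.18 ± 0.561 FPKM, and the gene that rose was Ptch1, a hedgehog receptor, from 0.488 ± 0.143 to 1.80 ± 0.108 FPKM. The control level of Actg2 stood far above those of Tpm2 (1.48 FPKM) and Des (0.968 FPKM) in the same list. Whether its reads came from myoid cells was not tested, and its log2 fold change of -6.70 pulled the list's mean below its median.

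**Figure D3:**
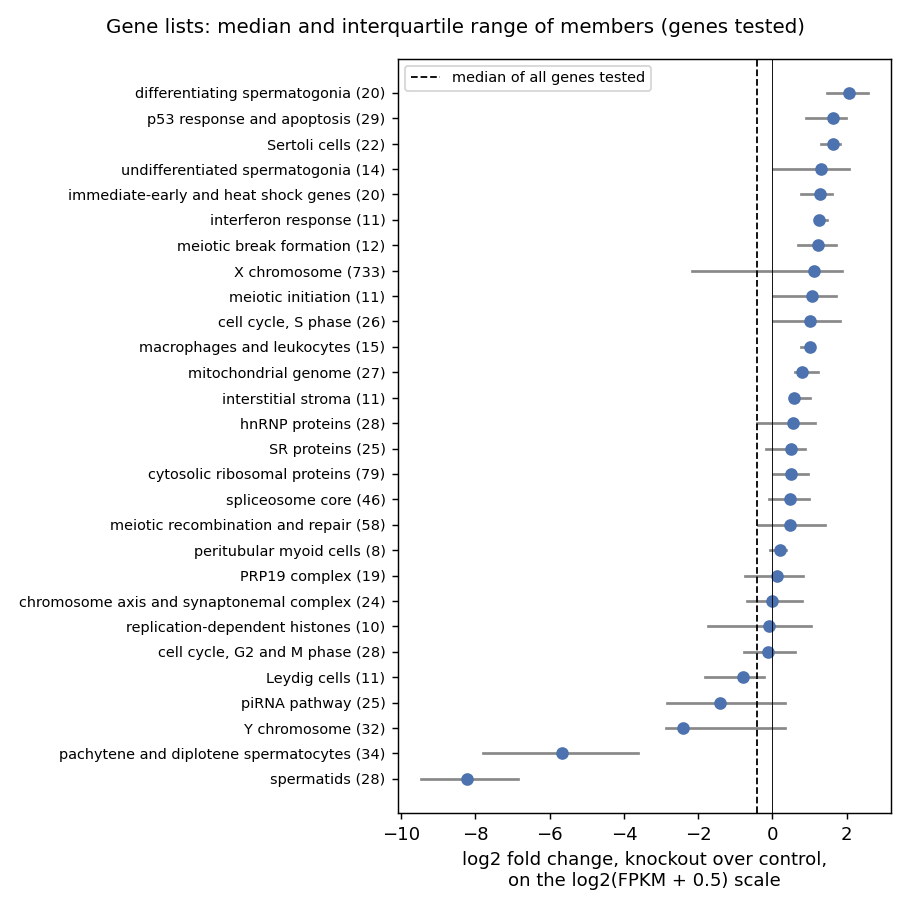
Median (point) and interquartile range (line) of the log2 fold change, knockout over control on the log2(FPKM + 0.5) scale, for each of 28 gene lists, with the number of genes tested in parentheses. The spermatid list lies lowest, at a median of -8.22, and differentiating spermatogonia highest, at 2.05, against a median of -0.41 for all genes (dashed line); the negative medians of the axis, G2 and M phase and histone lists turn positive with FPKM or reads rescaled to sum to 1000000 and under quantile normalization, and that of the Leydig list under the 2 rescalings.

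The median X-linked gene was higher in the knockout, relative to the control, than the median autosomal gene. Of 733 X-linked genes tested, 439 rose and 230 fell, or 441 and 230 when adjusted over the list alone. Among protein-coding genes the median log2 fold change was 1.30 for 569 genes on the X and -0.10 for 12122 on the autosomes, a difference of 1.40 that ranged from 1.34 to 1.54 under the 4 other scalings. In camera the adjusted p was 1.6e-05 for the X list on the upper side, and adjusted p = 0.493 with an estimated correlation. Fry placed the same list on the lower side, with an adjusted p of 0.0061. The list's median was 1.11 but its mean was -0.12, because its falls were larger than its rises: Hypm fell from 112.6 ± 9.99 FPKM to no reads in the knockout, at least 1356-fold lower with 3 reads over the group as the floor. On the Y chromosome 21 of 32 genes fell and 7 rose, as when adjusted over the list alone, with a median of -2.41 and a camera adjusted p of 0.279, or 0.012 with FPKM rescaled to sum to 1000000 and 0.040 with reads so rescaled. Gm20827, annotated as an unprocessed pseudogene, fell from 10.2 ± 2.06 FPKM to no reads, at least 146.3-fold lower by the same floor. It belongs to a family of near-identical Y-linked copies between which reads can be split. The 10 protein-coding Y genes tested had a median of 1.17, and with protein-coding genes alone the Y list lay on the upper side, with a camera adjusted p of 0.015.

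**Figure D4:**
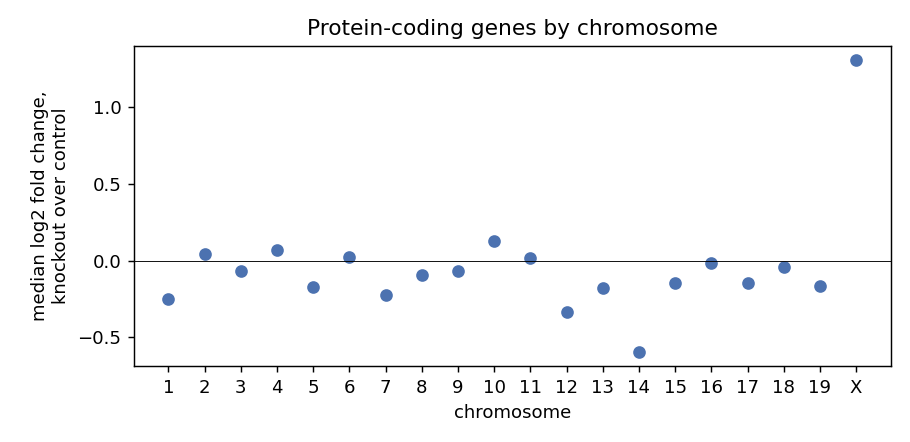
Median log2 fold change, knockout over control, of the protein-coding genes tested on each autosome and on the X chromosome. The X lies at 1.30, and the autosomes lie between -0.59 (chromosome 14) and 0.13 (chromosome 10); their sign depends on the scaling, since the autosomal median is -0.10 as deposited and 1.05 with FPKM rescaled to sum to 1000000.

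Transcripts of the mitochondrial genome took 1.28, 1.89 and 1.48% of the reads in the control libraries and 5.26, 5.37 and 4.52% in the knockout libraries. Of 27 mitochondrial genes tested, 16 rose and 0 fell, or 14 and 0 when adjusted over the list alone, with a camera adjusted p of 0.00037, and adjusted p = 0.493 with an estimated correlation. Genes of cytosolic ribosomal proteins rose in 47 of 79 cases and fell in 12, as when adjusted over the list alone. Rps2 rose from 54.8 ± 3.06 to 268.3 ± 33.2 FPKM, while Rpl39l, an autosomal copy of Rpl39 used in the testis, fell from 198.6 ± 16.3 to 30.8 ± 0.940 FPKM. For this list camera returned an adjusted p of 2.4e-05, and adjusted p = 0.493 with an estimated correlation.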

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

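The tests of other splits were chosen after the result was seen; the alternatives were planned, except reads rescaled to 1000000 and the recombination list without a doubtful member. Bcas2 stayed lower (log2 fold change -2.02 to -0.84) and Hnrnph1 higher (1.05 to 2.62) in every setting run, all past the threshold. At a mean of at least 5 FPKM, which tests fewer genes, 8547 genes passed, 3227 higher and 5320 lower. With an absolute log2 fold change of at least 1, 3920 were higher. Leaving out each library gave 14034 to 14293 genes. By camera with an estimated correlation 0 lists passed, and 0 had an unadjusted p under 0.05, against 20 with the preset one (18 up, 2 down) and 21 by fry (14 up, 7 down), which called the X chromosome, PRP19 and histone lists on the side opposite to camera. Among named genes 2268 comparisons kept direction and side of the threshold, 20 lost and 7 gained a call, and 1 turned: Syce3, at 0.0396 under quantile normalization. Among lists 513 did so, 29 lost and 11 gained a call, and in 4 camera's direction against the other genes turned, all uncalled as deposited: Leydig cells, whose medians stayed negative, at a mean of at least 5 FPKM (median -0.74) and without control replicate 2 (-0.64; range over left-out libraries -1.204 to -0.49), and the Y chromosome, whose medians turned positive, at a mean of at least 5 FPKM (0.74) and with protein-coding genes alone (1.17). Of the 10 protein-coding Y genes tested, 7 rose and 0 fell as deposited, so the 21 falls on the Y were all in other genes. The cause of the other turns was not tested. At a mean of at least 5 FPKM the interferon, stroma, myoid and histone lists had too few genes to test. The meiotic initiation call was lost in 7 settings besides the estimated correlation, at adjusted p of 0.055 to 0.116. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.12, -0.05 and -0.04, and with the replicate block 14294 genes and 20 lists passed. Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 14537 genes (6075 higher, 8462 lower) and the highest other 0 by limma, with 11 to 33 at unadjusted p under 0.05; 1 split was as large for each of these counts. For lists the real split gave 20 and the other splits gave 15 to 20, and 2 splits were as large. The count of camera calls with the preset correlation therefore does not set the real split apart.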

Other observations

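Several gene groups outside the comparisons above also moved. Of 1168 lincRNA genes tested with limma, 1040 were lower in the knockout and 80 higher, and of 719 antisense genes 586 were lower and 77 higher, with median log2 fold changes of -3.24 and -2.71. With FPKM rescaled to sum to 1000000, 996 lincRNA genes were still lower and 118 higher. Protein-coding genes were split evenly as deposited, with 5393 higher and 5656 lower, and 7992 higher and 3643 lower after that rescaling. All 11 interferon response genes tested, of 25 listed, rose, as when adjusted over the list alone, with Trim25 at 1.504 ± 0.514 FPKM in the controls and 7.18 ± 0.746 FPKM in the knockout (camera adjusted p of 0.0013, and adjusted p = 0.493 with an estimated correlation). The listed genes below the filter went both ways, as with Mx1 (1.04 FPKM in the controls and 0.349 in the knockout) and Usp18 (0.229 and 1.36 FPKM). Immediate-early and heat shock genes rose in 15 of 20 cases and fell in 3, as when adjusted over the list alone (camera adjusted p of 0.0091, and adjusted p = 0.626 with an estimated correlation). That call also ended under quantile normalization, at an adjusted p of 0.0504. Their share of reads was 0.206, 0.148 and 0.106% in knockout replicates 1, 2 and 3, where Sertoli markers took 0.605, 0.391 and 0.347% and macrophage markers 0.138, 0.0418 and 0.0529%. Gadd45b rose from 3.29 ± 0.482 to 18.4 ± 4.95 FPKM, while Klf4 fell from 68.2 ± 7.82 to 12.7 ± 4.99 FPKM and the chaperone gene Dnajb1 fell with a log2 fold change of -2.98. Replication-dependent histone genes rose in 5 of 10 cases and fell in 5, as when adjusted over the list alone, with a camera adjusted p of 0.596 on the upper side and a median of -0.10 that turned positive, between 0.65 and 0.93, with FPKM or reads rescaled to sum to 1000000 and under quantile normalization, while fry placed the list on the lower side with an adjusted p of 0.030. The lists of endothelial cells (1 of 4 genes rose and 1 fell, or 0 and 1 when adjusted over the list alone), erythroid cells (0 of 3 rose and 1 fell) and photoreceptors (1 of 4 rose and 2 fell) were too short for camera; the last 2 had the same counts when adjusted over the list alone.

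Of the tests that follow, those on gene length and on newly examined gene pairs were set before their results were seen; the others, on the size factor, the late germ cell lists, the somatic markers and the ribosomal genes, were chosen after, and the pair of Rpl36a and Rpl36al was taken out of the new pairs after 6 of 8 pairs had shown the pattern, because the value of Rpl36a had been seen earlier. The first pattern is the near absence of spermatid transcripts from the knockout libraries. With the size factor removed the list's median log2 fold change was -7.65, and with the trend of fold change with gene length removed it was -6.88, so neither accounts for it. A candidate explanation is that the knockout suspensions held few or no late germ cells, but no test here decides it: that 98.4% of the members of both late lists fell restates the pattern. The labels give no ages and describe isolated STRA8+ cells without saying how they were isolated, and a complete selection would leave few of the spermatid transcripts seen in the controls, so a difference in age, in selection or in development, and lower transcript levels within the same cells, all stay open and untested.

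The second pattern is that Sertoli markers rose relative to Leydig markers, whose share of reads was 0.0314% in the controls and 0.0443% in the knockout. A lower share of germ cell RNA would raise the markers of every other cell type alike. The list medians differed by 2.41 on the log2 scale, Sertoli minus Leydig, which restates the pattern. With each library left out they stayed apart, at 1.36 to 1.87 and -1.204 to -0.49, so the Sertoli and Leydig lists did not rise alike. A two-sided permutation over genes gave a p of 2e-05 from 100000 draws (6e-05 adjusted over 3 tests). Genes are not independent replicates, and camera estimated correlations of 0.789 and 0.752 within the lists. The permutation p therefore does not measure the spread between libraries. Apart from the chromosome lists, neither list shares genes with another list. The Sertoli marker Tsx is X-linked and so also belongs to the X list. The most abundant Sertoli marker, Clu, named after its value was seen, had 117.9 FPKM in the controls and 390.4 FPKM in the knockout. A change in Sertoli cells or in their share, or a different carry-over of interstitial cells into the suspensions, may contribute and was not tested. A complete selection of STRA8+ cells would remove both types, but the labels do not say how the cells were isolated. With FPKM rescaled to a common sum, the stroma, macrophage and myoid medians were 1.78, 2.22 and 1.33. The Sertoli and Leydig medians were then 2.83 and 0.31. A lower share of germ cell RNA may therefore still have contributed to a rise shared by several somatic lists, which was not tested.

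The third pattern is the higher median of X-linked genes. Apart from the pseudocount a per-library factor moves X-linked and autosomal genes alike, and the difference of medians lay between 1.34 and 1.54 under the 4 other scalings; a test of that factor was dropped after its value was seen. Whether X-linked genes particular to early germ cells alone were behind it was asked with X-linked ribosomal protein genes, used in all cells. The median of the 4 X-linked genes (Rpl10, Rpl36a, Rpl39 and Rps4x) was 1.47 above that of 75 autosomal ones, although 3 of the 4 had been seen to rise before the test. The higher level was thus not limited to genes particular to early germ cells. More germ cells from stages before meiosis silences the X would also raise these 4 genes, so the test cannot decide what set the median. A candidate explanation is a smaller share of cells in which meiosis has silenced the X, when autosomal retrocopies take over, but no test here decides it: in 71.4% of the newly examined pairs (5 of 7, or 4 with reads rescaled to 1000000) the X-linked parent rose and the retrocopy fell, yet 67.0% of X-linked protein-coding genes rose and late germ cell transcripts fell in any case. A failure of silencing within cells that reached that stage was not tested and would not by itself lower the retrocopies, and reads shared between parents and copies were not tested.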
